A study of Mus musculus with 4 samples.

How the data were processed

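Single-cell mRNA libraries and antibody tag libraries of sorted endothelial cells from neonatal mouse ears (postnatal day 8) were used, with 2 biological replicates of each kind. The cells had been enriched for CD31, stained and sorted, and libraries had been made with the 10x 3' v3 chemistry, per the labels' protocols. The mRNA matrices hold raw UMI counts per gene and cell that the authors made with Cell Ranger on mm10, per the submitters' processing notes, and the matrix headers name software version 3.0.2. Seurat 3.0.2 is named in those notes without a stated role. The aligner settings and the rule by which barcodes were kept before the counts were deposited are not given in the sources used here. The tag matrices hold deposited counts per antibody and barcode, with 3000 barcodes per library and a row of counts that matched no antibody. Whether tag counts are UMIs or reads, and which program counted them, is not given in the sources used here, so they are called tag counts.

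The choices of comparisons, tests, filters, markers, gene lists and the rule for named genes were made before the data were examined, as were all alternatives apart from 4 that are named with their effects. The matrices hold 31054 features. Barcodes with fewer than 500 detected genes (26 and 45 in libraries 1 and 2) or more than 10% mitochondrial UMIs (240 and 616) were left out, which kept 1500 and 2250. Doublets were called per library with Scrublet in scanpy 1.11.5 at an expected rate of 0.8% per 1000 cells, and 2 and 11 cells (0.347% of 3750) were removed. As a check, 1.01% and 1.22% of endothelial cells carried both Xist and Y-linked UMIs. No correction for free RNA was made. Among blood endothelial classes, the lymphatic gene Ccl21a had a UMI in 1.56% (tip-like) to 6.15% (vein-like) of the cells of a named class in library 1 and in 7.48% (artery-like) to 14.3% (tip-like) in library 2, against 83.2% and 97.0% of lymphatic-like cells. Median depths were 8473 and 9680 UMIs in tip-like and 8701 and 10104 UMIs in lymphatic-like cells.

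Counts were scaled to 10000 per cell and log-transformed, and the 1000 most variable genes across both libraries were taken after every gene of the fixed lists and the mitochondrial and ribosomal protein genes had been left out. Each gene was centred within its library. With 30 principal components and 15 neighbours, Leiden clustering at resolution 1.0 gave 16 clusters of all cells and 18 of the endothelial cells, and 1182 genes were used in either round. Clusters were named from 160 markers in 20 sets, by the markers among their leading genes or, in artery-like clusters 3 and 12 and lymphatic-like cluster 10, by high levels of several markers further down. Clusters of either round that were led by pericyte, erythroid, keratinocyte or immune markers were left out of the endothelial fits, except that cluster 2 of all cells (467 cells), with mast cell and macrophage markers among its leading genes, went into the endothelial round, where 10 immune-like cells formed a cluster of their own and were then left out. Other clusters without such markers, and cluster 15, where haemoglobin genes led together with tip markers, were kept under their number and counted as endothelial. A class entered a comparison with at least 20 cells in each library, which left clusters 15 and 17 out. Vein-like cluster 7 was led by Selp, Ackr1, Sele, Csf3 and Cxcl16, so inflammatory genes took part in naming it.

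UMIs were summed per library and class and tested with edgeR 4.0.16 (TMM scaling, low-count filter by class, quasi-likelihood test) in R 4.3.3, with Benjamini-Hochberg adjustment and 0.05 as the threshold. The design held the class and the library as a block, because each class was taken from both libraries and so from the same animals. The fit with the named classes left 4 residual degrees of freedom. Standard errors are the log2 change divided by the square root of the F value. Levels in CPM are TMM-scaled means of 2 libraries with their SD, and a level of several classes is the mean of their CPM, whereas the log2 change against several classes is taken against the mean of their log levels. As the same cells defined and tested the classes, named genes took no part in the clustering, and count splitting was run as an alternative. Named genes were those of the 5 tagged proteins, the 10 genes with the largest rise and the 10 with the largest fall among those that passed with an average log2 CPM of at least 5 and the same direction in both libraries, and up to 4 members of each list with the smallest adjusted p. Genes used for clustering, markers, predicted gene models, and mitochondrial and ribosomal protein genes were left out of the ranking. A gene that the rule names is not reported here. On simulated data with 200 changed genes drawn from the libraries' own means, 80.3% of genes changed 4 times and 61.2% of those changed 2 times were found in the comparison of artery-like with vein-like cells, with 4.46% false calls. The corresponding values were 90.9%, 74.6% and 6.67% for capillary-like cells, 87.9%, 70.1% and 10.4% for tip-like cells, and 90.9%, 86.6% and 7.19% for lymphatic-like cells. False calls thus lay above the nominal level in the last 3 of these. The simulation fixed the classes beforehand and had no clustering step, so these rates do not cover classes found in the same cells.

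The 17 fixed lists, holding 425 genes of which 422 were in the matrices, covered the tagged proteins, the cell cycle, the Notch pathway, VEGF and angiopoietin signalling, basement membrane and matrix, leukocyte adhesion and chemokines, antigen presentation, interferon response, glycolysis, fatty acid handling, flow response and vasomotor genes, junctions and barrier, TGF-beta and BMP signalling, Wnt signalling, axon guidance, endothelial transcription factors, and immediate-early and stress genes. They were tested with camera in limma 3.58.1 at its preset correlation of 0.01, with Benjamini-Hochberg adjustment within a comparison, and again with the correlation estimated per list. Gene positions came from GENCODE vM21 on GRCm38, by identifier, where 401 of 402 identifiers looked up were found. The identifier not found was that of a feature named Ccl21a, a symbol that several features share.

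For the share of dividing cells, every cell was thinned at random to 3000 UMIs and cells below that depth were left out. Shares carry exact Clopper-Pearson 95% intervals, which cover counting error only. Tag barcodes were joined to the mRNA barcodes of the same replicate. Of the mRNA barcodes, 97.1% and 92.8% had tag data, which covered 1354 and 1923 endothelial cells, and 3 tag barcodes of each library also occurred in the mRNA library of the other replicate. Coverage differed between classes: in library 2 it was 504 of 603 lymphatic-like and 274 of 294 artery-like cells. In the same library it was 127 of 127 vein-like and 195 of 196 tip-like cells. Tag ratios were taken within a library. Tag counts that matched no antibody (7.91% and 11.5%) were left out.

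Alternatives changed 1 choice at a time: a stricter cell filter (1000 genes, 5% mitochondrial UMIs) or none, doublets kept, Leiden resolution 0.5 or 2.0, 2000 variable genes, no library centring, DESeq2 1.42.0 size factors or Wald test, no low-count filter, no replicate block, count splitting, equal cell numbers, each library left out, fry in place of camera, no thinning, another call of dividing cells, and other scalings of the tags. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, igraph 0.11.9 and matplotlib 3.10.9 were used.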

Results

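Endothelial cells from the ears of neonatal C57BL/6 mice at postnatal day 8 were measured by single-cell RNA sequencing and, in the same cells, with oligonucleotide-tagged antibodies against 5 surface proteins and with 2 isotype control antibodies. The cells had been sorted alive for CD31 and for a red fluorescent reporter switched on by Cdh5-driven recombination. The 2 libraries are biological replicates per the labels and form 1 group, so each comparison set endothelial classes against each other within a library, and every p-value rests on 2 libraries. The adult and adult wounded samples of the series were not analysed here. Library 1 held 1745 barcodes and 15989249 unique molecular identifiers (UMIs), and library 2 held 2877 barcodes and 26675353 UMIs. After filtering, 1498 and 2239 cells were kept, with medians of 8459 and 8982 UMIs per cell. The antibody libraries held 301923 and 527008 tag counts over 3000 barcodes each.

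The composition of the sorted cells was examined first. Endothelial cells made up 92.1% of the kept cells in library 1 (exact Clopper-Pearson 95% interval 90.6 to 93.4%) and 91.8% in library 2 (90.6 to 92.9%). The 16 and 32 erythroid-like cells were not counted as endothelial, although Pecam1 reached 1187 and 1176 CPM in them, near the 1203 and 1291 CPM of capillary-like cells. Nor were the pericyte-like cells, most of which also carried Pecam1 and Cdh5 UMIs. Lymphatic-like cells had the largest mean share in the planned clustering (25.7% ± 5.22 of endothelial cells; SD, n = 2), followed by capillary-like (18.4% ± 2.60), artery-like (16.3% ± 2.80), vein-like (9.58% ± 4.80) and tip-like cells (9.41% ± 0.186). Tip-like cells carried the mRNA of genes known from the leading cells of vascular sprouts, such as Esm1 and Apln. Esm1 was also among the leading genes of capillary-like cluster 8. Vein-like cells fell from 12.97% of endothelial cells in library 1 (11.2 to 14.9%) to 6.18% in library 2 (5.18 to 7.31%), whereas lymphatic-like cells were more frequent in library 2 (29.3%, 27.4 to 31.4%) than in library 1 (22.0%, 19.8 to 24.2%). Among the classes that the markers did not name, cluster 5, led by Icam1, Sele, Atf3 and Tnfaip3, held 5.22% and 12.2% of endothelial cells in libraries 1 and 2. Cluster 6, led by Rrm2, Cdk1 and Top2a, held 7.75% and 8.76%, and cluster 14, led by Ccnb2 and Cenpa, held 2.17% and 1.07%. Differences between classes in their mean share were compared without a test, and the intervals cover counting error only. The tip-like and capillary-like shares moved with the clustering resolution: at the lower resolution they were 16.1% and 23.8%. Capillary-like cells came before lymphatic-like cells with the stricter cell filter (25.1% against 16.2%), with no cell filter (39.8% against 23.3%) and with clustering without cell cycle genes (29.3% against 25.7%).

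**Figure D1:**
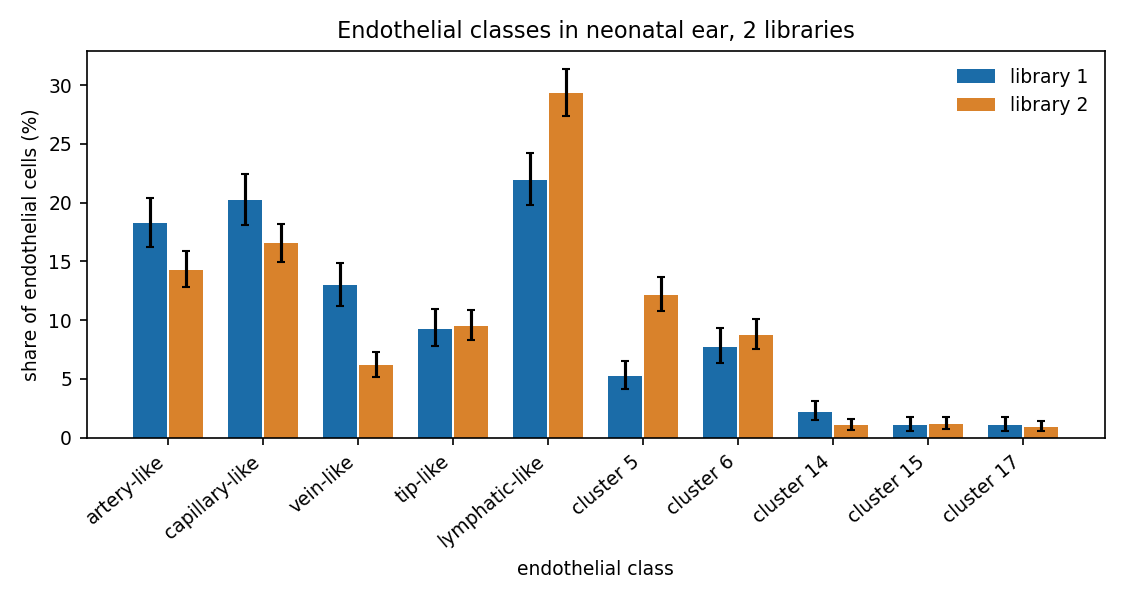
Share of endothelial cells (%, vertical axis) in each endothelial class (horizontal axis) for libraries 1 and 2 (bars), with exact 95% intervals as error bars. Tip-like cells held 9.28% and 9.54%, while vein-like cells held 12.97% and 6.18%.

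Artery-like cells were compared with vein-like cells to ask what distinguishes the ends of the arteriovenous axis. Artery-like cells carried more mRNA of the netrin receptor Unc5b, which reached 192 ± 18.6 counts per 1e+06 (CPM; SD, n = 2) in artery-like and 2.03 ± 1.46 CPM in vein-like cells (log2 change 6.36 ± 0.27 SE, edgeR adjusted p = 4.61e-09). The vein-like level of Unc5b lay near what 3 UMIs give in that class (1.888 and 2.744 CPM in libraries 1 and 2), so the size of its fold is uncertain. The chemokine Cxcl12 reached 1482 ± 249 CPM against 20.7 ± 9.61 CPM (log2 6.12 ± 0.19 SE, adjusted p = 1.08e-09). Artery-like cells also had more Sema7a, Fn1, Tgfb2 and Cldn5 mRNA, with log2 changes of 4.66, 3.88, 2.83 and 2.45. Cldn5 encodes a tight-junction protein of the endothelial barrier. Vein-like cells carried more mRNA of the leukocyte-capturing selectin Sele (1180 ± 851 CPM against 3.95 ± 3.38 CPM; log2 -8.14 ± 0.28 SE, adjusted p = 1.29e-09), of Nrp2 (log2 -3.92), of the water channel Aqp1 (log2 -3.12) and of Procr (log2 -2.82). Icam1 and Vcam1, which encode adhesion receptors for leukocytes, were higher in vein-like cells (log2 -2.10 ± 0.24 SE, adjusted p = 3.55e-05, and log2 -1.70 ± 0.23 SE, adjusted p = 0.000135). Cxcr4, the receptor for Cxcl12, was higher in artery-like cells (32.9 ± 0.987 CPM, adjusted p = 1.96e-05), with no fold given because vein-like cells held 1 UMI in each library. Kdr, the gene of VEGFR2, did not pass (log2 -0.02 ± 0.10 SE, adjusted p = 0.95).

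Among gene groups in the comparison of artery-like with vein-like cells, the Notch pathway, which directs arterial identity, was higher in artery-like cells. Of its 18 tested genes 10 rose, 1 fell and 7 did not pass, and 11 passed when adjusted over the list alone. Dll4, Notch4, Jag2 and Jag1 rose by log2 3.06, 3.00, 2.83 and 2.06, and the list passed camera (adjusted p = 2.42e-05, adjusted p = 0.0941 with an estimated correlation). Of 47 basement membrane and matrix genes 19 rose, 7 fell and 21 did not pass (29 passed adjusted over the list alone), with Col18a1 (log2 2.80) and Nid2 (log2 2.08) higher and Fbn1 (log2 -2.38) lower in artery-like cells. This list passed as well (adjusted p = 0.000662, adjusted p = 0.0941 with an estimated correlation). Of 28 leukocyte adhesion and chemokine genes 13 were higher in vein-like and 5 in artery-like cells, and the list did not pass (adjusted p = 0.0614). Glycolysis genes (2 rose, 1 fell, of 17, adjusted p = 0.491), junction and barrier genes (5 rose, 2 fell, of 19, adjusted p = 0.0665) and axon guidance genes (4 rose, 5 fell, of 20, adjusted p = 0.491) did not pass either, nor did the 4 tested genes of the tagged proteins (adjusted p = 0.491). The vein-like cells were led by Selp, Ackr1, Sele, Csf3 and Cxcl16, several of them genes of inflammation. Immediate-early and stress genes were higher in library 2 in artery-like (21 of 22 genes, median log2 ratio of library 2 to library 1 0.50) and in vein-like cells (20 of 22, median 0.59). Icam1, which is not in that list, ranged from 184 to 723 CPM between libraries in artery-like and from 915 to 2720 CPM in vein-like cells. A link between these shifts was not tested. Median, mean and test did not share a sign for TGF-beta and BMP signalling (median -0.15, mean -0.15, test upward), Wnt signalling (median -0.05, mean 0.04, upward), glycolysis (0.12, -0.02, upward), VEGF and angiopoietin signalling (0.00, -0.30, downward), the tagged proteins (-0.86, 0.39, downward) and endothelial transcription factors (0.03, 0.01, downward). In all, 1783 of 10852 genes passed, 903 higher in artery-like and 880 higher in vein-like cells, and 1396 of them had no part in the clustering. The DESeq2 Wald test passed 1000 genes. In GRCm38 (mm10), GENCODE vM21 lists Unc5b (ENSMUSG00000020099) as a protein-coding gene on chromosome 10 from 60762593 to 60831581. Cxcl12 (ENSMUSG00000061353) lies on chromosome 6 from 117168535 to 117181367 and Sele (ENSMUSG00000026582) on chromosome 1 from 164048234 to 164057677.

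**Figure D2:**
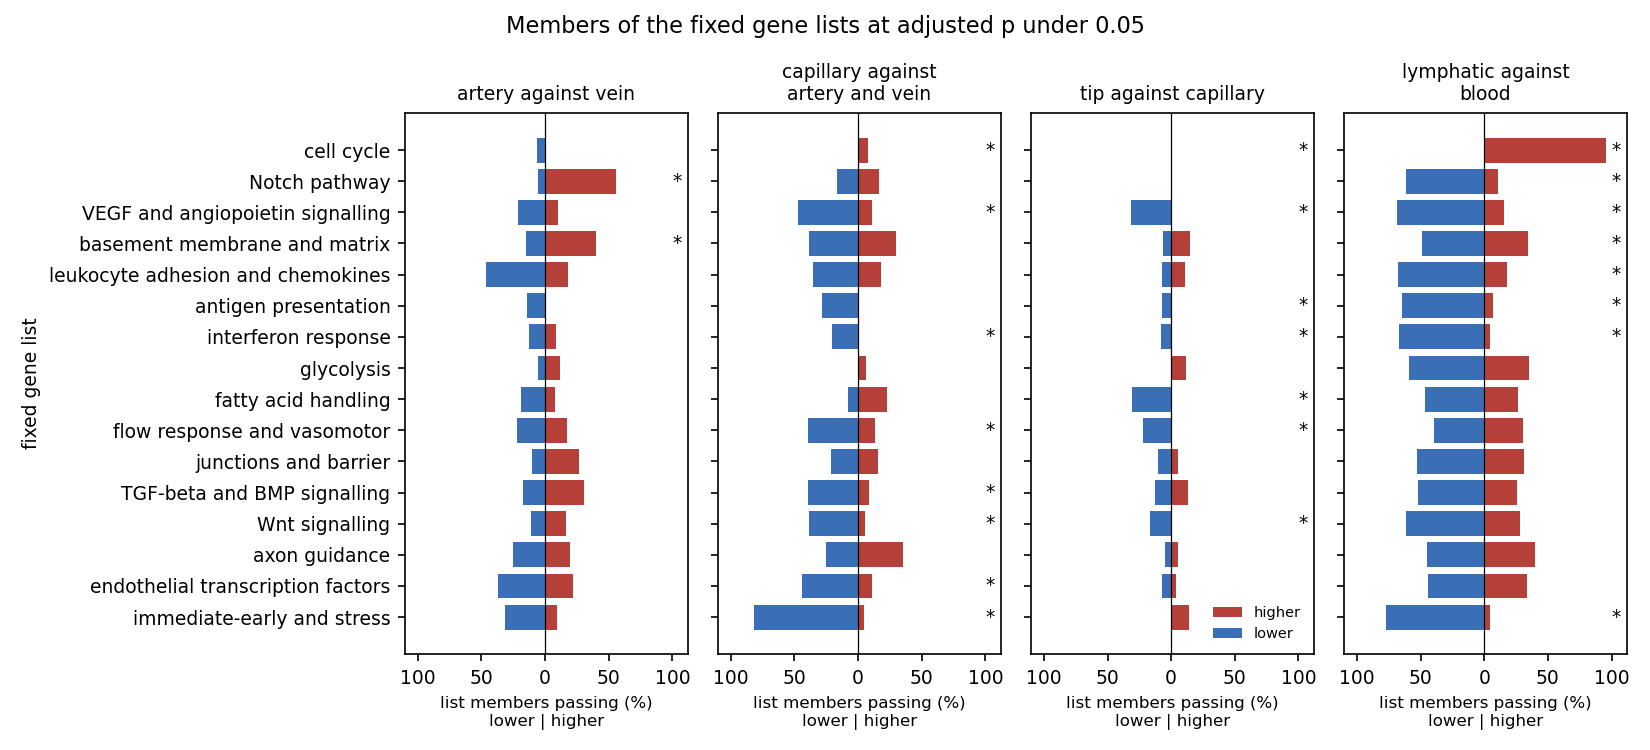
Percent of the tested genes of each fixed list (vertical axis) that were higher (red, to the right) or lower (blue, to the left) at the adjusted threshold in 4 comparisons (panels); asterisks mark lists that passed camera at its preset correlation. Of 18 Notch pathway genes 10 were higher in artery-like and 11 were lower in lymphatic-like cells. The cell cycle bar in the lymphatic panel comes from keeping the dividing cluster 10 in that class while the dividing blood cells were left out.

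Capillary-like cells were compared with the mean log level of artery-like and vein-like cells, to set capillaries against larger vessels. Capillary-like cells carried more mRNA of the basement membrane genes Nid2 (256 ± 39.4 CPM against a mean of 89.6 ± 13.8 CPM; SD, n = 2), Col15a1 and Lamb1 (log2 1.87, 1.76 and 1.69), of Tspan15 (log2 2.30 ± 0.13 SE, edgeR adjusted p = 2.56e-07) and of the mechanosensitive channel gene Piezo2 (log2 1.91). Kdr was higher in capillary-like cells, at 633 ± 57.7 CPM against 345 ± 49.5 CPM (log2 0.88 ± 0.08 SE, adjusted p = 1.13e-05). Mgp and Eln, which encode matrix proteins of vessel walls, were lower: Mgp reached 2.20 ± 0.791 CPM against 765 ± 454 CPM (log2 -8.34 ± 0.52 SE, adjusted p = 3.31e-07), Eln 34.2 ± 2.90 CPM against 2169 ± 1152 CPM, and Mmp2, Fbln2 and Fbn1 were lower by log2 -5.87, -3.12 and -2.94. The basement membrane and matrix list as a whole did not pass (14 higher, 18 lower, of 47, camera adjusted p = 0.18). The vasoconstrictor gene Edn1 (log2 -3.57), Il6 (log2 -3.42) and Vegfc (log2 -3.03) were also lower. Icam1 (log2 -0.96, adjusted p = 0.00781) and Vcam1 (log2 -3.36, adjusted p = 2.99e-06) were lower in capillary-like cells. Cxcr4 lay between the larger vessels, at 14.7 ± 2.66 CPM in capillary-like, 32.9 ± 0.987 CPM in artery-like and 0.803 ± 0.271 CPM in vein-like cells.

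Immediate-early and stress genes had the smallest p of camera at its preset correlation in the comparison of capillary-like cells with larger vessels: 18 of 22 were lower, 1 was higher and 3 did not pass (20 passed adjusted over the list alone), with Nr4a1, Atf3 and Ier3 lower by log2 -1.73, -1.56 and -1.27 (camera adjusted p = 6.12e-11, adjusted p = 0.288 with an estimated correlation). Cluster 5, led by Icam1, Sele and Atf3, was not part of this fit, so cells high in such genes may have been taken out of the capillary-like class. At the lower clustering resolution cluster 5 did not form, and capillary-like cells of library 2 went from 340 to 570. Atf3 was then not lower (log2 0.16). How far the lower levels of this list and of Icam1 follow from that split was not tested. Most genes of this list were also higher in library 2 than in library 1 in capillary-like cells (18 of 22). The flow-responsive transcription factors Klf2 (log2 -1.21) and Klf4 (log2 -1.23) were lower, among 9 lower and 3 higher of 23 flow response genes. Of 27 endothelial transcription factors 12 were lower and 3 higher, led by Gata6 (log2 -4.10) and Foxp1 (log2 -1.36). VEGF and angiopoietin signalling (9 lower, 2 higher, of 19; Ptprb log2 -1.40 and Robo4 log2 0.90) and interferon response (5 lower of 24) were lower too, and each of these 4 lists passed (adjusted p = 0.000728, adjusted p = 0.288 with an estimated correlation). Cell cycle genes were higher by the list test although 46 of 50 did not pass singly (adjusted p = 0.000728, adjusted p = 0.584 with an estimated correlation). That list cannot compare division between these classes, because dividing blood cells had been placed in clusters 6 and 14. TGF-beta and BMP signalling (9 lower, 2 higher, of 23; Bmp2 log2 -3.68) and Wnt signalling (7 lower, 1 higher, of 18; Dkk2 log2 -3.82) were lower (adjusted p = 0.0103 and 0.0116, adjusted p = 0.288 with an estimated correlation for both). Median, mean and test did not share a sign for axon guidance (median 0.08, mean -0.56, test upward), junctions and barrier (0.08, -0.34, upward) and antigen presentation (-0.08, 0.14, downward). In all, 1553 of 10852 genes passed (719 higher, 834 lower), of which 1205 had no part in the clustering. The Wald test passed 790, and at the lower clustering resolution Icam1 was higher in capillary-like cells (log2 0.48). GENCODE vM21 lists Nid2 (ENSMUSG00000021806) as a protein-coding gene on chromosome 14 from 19751265 to 19811787 of GRCm38 (mm10) and Mgp (ENSMUSG00000030218) on chromosome 6 from 136872435 to 136875823.

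Tip-like cells were compared with capillary-like cells, since the purpose in the series title is the heterogeneity of endothelium in growing vessels. Tip-like cells carried more mRNA of Cxcr4 (42.8 ± 1.69 CPM against 14.7 ± 2.66 CPM; SD, n = 2; log2 1.55 ± 0.25 SE, edgeR adjusted p = 0.00327), a chemokine receptor of migrating cells. They also carried more of the tetraspanin Cd82 (log2 1.82 ± 0.22 SE, adjusted p = 0.000324), of Arl4c (134 ± 42.8 CPM against 47.2 ± 4.29 CPM, adjusted p = 7.09e-05) and the transcription factor Prdm1 (log2 1.51). Fewer transcripts were found of Vegfc (log2 -2.89), Fbln2 (38.4 ± 5.63 CPM against 165 ± 50.8 CPM; log2 -2.06 ± 0.22 SE, adjusted p = 0.000162), Chp2 (log2 -2.15) and the VEGF decoy receptor Flt1 (log2 -1.15). Kdr (log2 -0.02, adjusted p = 0.967), Icam1 (log2 -0.19, adjusted p = 0.788) and Vcam1 (log2 0.79, adjusted p = 0.433) did not pass. The chemokine Ccl2 was higher in tip-like cells (log2 4.21 ± 0.53 SE, adjusted p = 0.000491), and at the lower clustering resolution it was not (log2 -0.30).

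Of the list named fatty acid handling, which also holds Aqp1, Aqp7 and Meox2 with a less direct link to fatty acids, 8 of 26 genes fell in tip-like cells, none rose, and 9 passed adjusted over the list alone, with Slc27a3 and Lipe lower by log2 -2.07 and -1.66 (camera adjusted p = 7.1e-05, adjusted p = 0.148 with an estimated correlation). Interferon response genes were lower as a list (2 of 24 fell, adjusted p = 7.1e-05, adjusted p = 0.453 with an estimated correlation). VEGF and angiopoietin signalling (6 of 19 fell, among them Ptprb with log2 -1.26, adjusted p = 0.00187, adjusted p = 0.507 with an estimated correlation) was lower. So was flow response (5 of 23 fell, with Klf4 log2 -1.03 and Klf2 log2 -0.72, adjusted p = 0.00187, adjusted p = 0.453 with an estimated correlation). Wnt signalling (3 of 18 fell, adjusted p = 0.00457, adjusted p = 0.453 with an estimated correlation), antigen presentation (1 of 14 fell, adjusted p = 0.00782, adjusted p = 0.752 with an estimated correlation) and the cell cycle (0 of 50 genes passed in edgeR and 11 were lower at an unadjusted p under 0.05, adjusted p = 0.0138, adjusted p = 0.799 with an estimated correlation) were lower as lists. The cell cycle list cannot compare division between these classes, because dividing blood cells had been placed in clusters 6 and 14. With clustering without cell cycle genes, the share of dividing cells was 20.6% in tip-like and 19.7% in capillary-like cells. Among basement membrane and matrix genes, Nid2 (log2 0.95) and Lamb1 (log2 0.75) rose and Lamb2 (log2 -1.11) fell, 7 rose and 3 fell of 47, and the list did not pass (adjusted p = 0.468). The glycolysis genes Pkm (log2 0.74) and Pfkp (log2 0.62) rose, and that list did not pass (adjusted p = 0.468). Immediate-early and stress genes were higher in library 2 than in library 1 in tip-like cells (21 of 22 genes, median log2 ratio 0.57). Median, mean and test did not share a sign for the Notch pathway (median -0.09, mean -0.01, test upward), basement membrane and matrix (0.09, -0.08, upward), glycolysis (-0.03, -0.01, upward), TGF-beta and BMP signalling (-0.16, 0.02, downward) and axon guidance (0.16, -0.07, upward). In all, 466 of 10852 genes passed, 254 higher and 212 lower, and 335 of them had no part in the clustering. That count ranged from 217 without the library block and 229 with the Wald test to 838 without the low-count filter, and was 762 and 303 at the lower and higher clustering resolution and 831 with the cells split by sex. GENCODE vM21 lists Cxcr4 (ENSMUSG00000045382) as a protein-coding gene on chromosome 1 from 128588199 to 128592293 of GRCm38 (mm10) and Cd82 (ENSMUSG00000027215) on chromosome 2 from 93419111 to 93463140.

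Lymphatic-like cells were compared with the mean log level of the 4 named blood endothelial classes, because lymphatic cells also carry CD31 and Cdh5. Lymphatic-like cells carried more mRNA of the semaphorin Sema3d (116 ± 9.73 CPM against 0.764 ± 0.0351 CPM; SD, n = 2; log2 8.08 ± 0.19 SE, edgeR adjusted p = 5.16e-12), of the transcription factor genes Maf (247 ± 0.589 CPM against 2.02 ± 1.45 CPM; log2 6.86 ± 0.19 SE, adjusted p = 5.93e-12), Foxc2 (log2 5.90) and Tbx1 (log2 4.49), and of Nrp2 (log2 2.62), which encodes a co-receptor for lymphatic growth factors. The blood level of Sema3d lay below what 3 UMIs give in any named blood class (0.981 to 2.744 CPM), and that of Maf lay within that range. The sizes of their folds are thus uncertain. They carried little of the blood vascular genes Nrp1 (2.83 ± 1.26 CPM against 533 ± 15.8 CPM; log2 -7.66 ± 0.17 SE, adjusted p = 9.65e-13), Flt1 (log2 -6.32), Jam2 (log2 -6.92), Cd34 (log2 -4.58) and Epas1 (log2 -3.25). All 4 tested genes of the tagged proteins were lower: Icam1 by log2 -1.35, Vcam1 by -2.65 and Kdr by -0.34, while for Cxcr4, with 0 and 7 UMIs in lymphatic-like cells of libraries 1 and 2, no fold is given (adjusted p = 0.000429).

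The cell cycle list cannot compare division between lymphatic-like cells and blood endothelium, because lymphatic-like cells included the dividing cluster 10 while clusters 6 and 14 were not part of the blood mean. In this fit 48 of 50 genes rose, 2 did not pass, and all 50 passed adjusted over the list alone (camera adjusted p = 7.01e-18, adjusted p = 0.287 with an estimated correlation). Ube2c, Cenpf and Birc5, higher by log2 4.31, 3.78 and 3.54, did not pass once cluster 10 was removed (log2 0.33, 0.22 and 0.33). Leukocyte adhesion and chemokine genes were lower (19 fell, 5 rose, of 28, adjusted p = 1.79e-08, adjusted p = 0.248 with an estimated correlation), among them Cd34, Jam2 and Cxcl12. Notch pathway genes were lower (11 fell, 2 rose, of 18; Mfng log2 -6.19, Notch4 log2 -4.78, adjusted p = 6.23e-05, adjusted p = 0.248 with an estimated correlation). Antigen presentation (9 fell, 1 rose, of 14; H2-K1 log2 -1.63) and immediate-early and stress genes (17 fell, 1 rose, of 22; Ier3 log2 -3.10) were lower (adjusted p = 0.000114 for both, adjusted p = 0.37 with an estimated correlation). VEGF and angiopoietin signalling (13 fell, 3 rose, of 19, adjusted p = 0.000183) and interferon response (16 fell, 1 rose, of 24, adjusted p = 0.000519) were lower (adjusted p = 0.287 with an estimated correlation for both). Basement membrane and matrix genes were lower as a list (23 fell, 16 rose, of 47; Sparc log2 -3.85, Timp2 log2 2.07, adjusted p = 0.0236, adjusted p = 0.248 with an estimated correlation). In all, 5075 of 10852 genes passed, 2562 higher and 2513 lower, and 4458 of them had no part in the clustering. The Wald test passed 3109. GENCODE vM21 lists Sema3d (ENSMUSG00000040254) as a protein-coding gene on chromosome 5 from 12383385 to 12588948 of GRCm38 (mm10) and Nrp1 (ENSMUSG00000025810) on chromosome 8 from 128358604 to 128503363.

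Cluster 5, which the markers did not name, was compared with the mean log level of the 4 named blood endothelial classes. It carried more mRNA of genes of vascular inflammation: Icam1 reached 1960 ± 921 CPM against 769 ± 538 CPM (SD, n = 2; log2 1.81 ± 0.18 SE, edgeR adjusted p = 3.84e-05), Cxcl10 401 ± 23.5 CPM against 107 ± 92.9 CPM (log2 3.29 ± 0.32 SE, adjusted p = 3.09e-05). Il6, Tnfaip3 and Atf3 were higher by log2 1.67, 1.48 and 1.64. Sele reached 567 ± 33.3 CPM, against 1180 ± 851 CPM in vein-like and 3.95 ± 3.38 CPM in artery-like cells. Fn1, Col18a1, Notch4 and Jag1 were lower by log2 -1.77, -1.34, -0.72 and -0.61. All 4 were higher in artery-like than in vein-like cells, and artery-like cells were part of the mean. Their lower level may thus reflect that class, and cluster 5 was not compared with capillary-like or vein-like cells alone. Immediate-early and stress genes were higher (15 of 22 rose, 7 did not pass; 20 passed adjusted over the list alone; camera adjusted p = 6.83e-24, adjusted p = 0.0947 with an estimated correlation). Leading genes of cluster 5 outside the fixed lists, such as Irf1 and Noct, took part in the clustering. The rises of Icam1, Atf3 and Tnfaip3 and of the immediate-early and leukocyte adhesion lists thus follow in part from how the cluster was formed. They are no independent evidence. Immediate-early and stress genes were higher in library 2 than in library 1 within cluster 5 (21 of 22), and the cluster's share was higher in library 2. Leukocyte adhesion and chemokine genes were higher (10 rose, 3 fell, of 28, adjusted p = 6.48e-08, adjusted p = 0.0947 with an estimated correlation), as were antigen presentation (2 of 15 rose, adjusted p = 4.75e-05, adjusted p = 0.63 with an estimated correlation) and cell cycle genes (1 of 50 rose, adjusted p = 0.000197, adjusted p = 0.681 with an estimated correlation). With dividing blood cells placed in clusters 6 and 14, the cell cycle list cannot compare division here. Matrix genes (8 fell, 1 rose, of 47, adjusted p = 0.000424, adjusted p = 0.0947 with an estimated correlation) and the Notch pathway (3 fell, 1 rose, of 18, adjusted p = 0.0192, adjusted p = 0.139 with an estimated correlation) were lower. Both lists were higher in artery-like than in vein-like cells, so the same limit holds for them. Median, mean and test did not share a sign for glycolysis (median -0.06, mean 0.10, test downward), the tagged proteins (-0.02, 0.08, upward), flow response (0.01, -0.09, downward) and TGF-beta and BMP signalling (-0.01, 0.02, upward). In all, 441 of 10934 genes passed (290 higher, 151 lower). That count was 70 without the library block, 228 with the Wald test, 273 at the higher clustering resolution, 677 with count splitting, 862 without the low-count filter and 1181 with called doublets kept. GENCODE vM21 lists Icam1 (ENSMUSG00000037405) as a protein-coding gene on chromosome 9 from 21015985 to 21028817 of GRCm38 (mm10).

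Clusters 6 and 14, both blood endothelial and both led by cell cycle genes, were compared with the same mean of named blood classes. Leading genes outside the fixed lists, such as Pbk in cluster 6 and Knstrn in cluster 14, took part in the clustering. The cell cycle list results of both clusters thus follow in part from how the clusters were formed and are no independent evidence. In cluster 6 all 50 cell cycle genes rose, with Rrm2 and Ccnb1 higher by log2 5.41 ± 0.14 SE and 6.04 ± 0.16 SE (edgeR adjusted p = 4.55e-13 for both), and the list passed camera (adjusted p = 1.26e-69, adjusted p = 0.0305 with an estimated correlation). The glycolysis list did not pass (8 rose, 1 fell, of 17, adjusted p = 0.17). Flow response (11 of 23 fell; Klf4 log2 -0.52, adjusted p = 0.00291), immediate-early and stress (16 fell, 1 rose, of 22, adjusted p = 0.00127) and interferon response (7 of 24 fell, adjusted p = 0.00369) were lower in cluster 6. VEGF and angiopoietin signalling (7 fell, 1 rose, of 19) and endothelial transcription factors (6 of 27 fell) were lower too, both with adjusted p = 0.0165. For these 5 lists the adjusted p = 0.405 with an estimated correlation. TGF-beta and BMP signalling was lower as well (7 fell, 1 rose, of 23, adjusted p = 0.0205, adjusted p = 0.284 with an estimated correlation). For antigen presentation the median (0.18) and mean (0.24) were positive and the test pointed downward. In all, 3333 of 10986 genes passed in cluster 6 (2004 higher, 1329 lower; 1869 with the Wald test).

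In cluster 14 the late cell cycle genes Ccnb2 (378 ± 4.39 CPM against 11.3 ± 3.48 CPM; SD, n = 2; log2 5.17 ± 0.26 SE, edgeR adjusted p = 1.86e-09), Birc5 (log2 4.81) and Hmgb2 (log2 2.79) were higher than in the named blood classes, and 23 of 50 cell cycle genes rose (camera adjusted p = 1.96e-28, adjusted p = 0.155 with an estimated correlation). This rise, too, follows in part from how the cluster was formed. Klf4, Klf2 and Junb were lower by log2 -1.75, -1.52 and -1.36, and Icam1 by log2 -1.22. Immediate-early and stress genes fell (17 of 22, adjusted p = 1.61e-16, adjusted p = 0.155 with an estimated correlation), as did leukocyte adhesion genes (4 of 28, adjusted p = 0.000839, adjusted p = 0.215 with an estimated correlation). Glycolysis (7 of 17 rose; Gapdh log2 0.66, Pkm log2 0.68, adjusted p = 0.000491, adjusted p = 0.139 with an estimated correlation) and fatty acid handling (5 of 26 rose; Fabp4 log2 1.12, adjusted p = 0.022, adjusted p = 0.155 with an estimated correlation) were higher. Notch pathway (5 of 18 fell, adjusted p = 0.0192, adjusted p = 0.155 with an estimated correlation) and matrix genes (12 fell, 4 rose, of 47, adjusted p = 0.00343, adjusted p = 0.155 with an estimated correlation) were lower than in a mean that includes artery-like cells, where both lists were higher than in vein-like cells. TGF-beta and BMP signalling (5 of 23 fell, adjusted p = 0.00343, adjusted p = 0.139 with an estimated correlation) and transcription factor genes (7 of 27 fell, adjusted p = 0.000807, adjusted p = 0.219 with an estimated correlation) fell as well. So did flow response (3 fell, 1 rose, of 23, adjusted p = 0.0134) and junction genes (2 of 19 fell, adjusted p = 0.023), and each had adjusted p = 0.298 with an estimated correlation. VEGF and angiopoietin signalling (3 of 19 fell, adjusted p = 0.0192) and interferon response (0 of 24 genes passed in edgeR and 3 were lower at an unadjusted p under 0.05, adjusted p = 0.0134) were lower too, with adjusted p = 0.324 with an estimated correlation for both. In all, 1069 of 10867 genes passed in cluster 14 (675 higher, 394 lower), and the count was 508 with equal cell numbers per class and 1718 at the higher clustering resolution. Cluster 14 had 30 and 22 cells in libraries 1 and 2.

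The share of dividing cells was compared between classes as the share of cells with at least 1 UMI of Mki67 or Top2a after every cell had been thinned to 3000 UMIs, a depth below which 45 and 49 endothelial cells of libraries 1 and 2 were left out. Among blood endothelial cells 13.6% (11.6 to 15.9%) and 16.3% (14.4 to 18.3%) carried such a UMI, and among lymphatic-like cells 12.7% (9.12 to 16.97%) and 15.7% (12.9 to 18.9%). Artery-like (3.00% and 3.96%), capillary-like (3.38% and 6.14%), vein-like (5.62% and 1.60%) and tip-like cells (3.18% and 3.13%) had low shares, which say little about division in these classes, since dividing blood cells had been placed in clusters 6 and 14. With clustering without cell cycle genes, an alternative chosen after seeing the data, artery-like cells had 4.25% (2.14 to 7.47%) and 7.51% (4.77 to 11.1%), capillary-like cells 19.7% as the mean of libraries (intervals 16.2 to 24.2% and 16.1 to 22.9%), and tip-like cells 18.7% (10.6 to 29.3%) and 22.5% (15.1 to 31.4%). Lymphatic-like cells outside cluster 10 had 2.64% and 4.85%, whereas cluster 10 had 88.6% and 84.1% and cluster 6 had 91.3% and 90.3%. In cluster 14, 33.3% and 22.7% of cells carried such a UMI after thinning and 83.3% and 59.1% before. Dividing cells were therefore mostly in clusters of their own in both blood and lymphatic endothelium. No class is known to lack these genes, so the share that free RNA gives is not known. The lowest shares, 2.64% (1.07 to 5.37%) in lymphatic-like cells outside cluster 10 of library 1 and 1.60% (0.194 to 5.66%) in vein-like cells of library 2, leave room for a background of that size at the common depth of 3000 UMIs. Without thinning, blood endothelial cells had 19.6% and 25.6% and lymphatic-like cells 17.5% and 24.2%. In the capillary-like class 13 and 14 cells, in the artery-like 19 and 16, in the vein-like 1 and 2, in the tip-like 2 and 4 and in the lymphatic-like 3 and 5 were left out by the thinning.

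**Figure D3:**
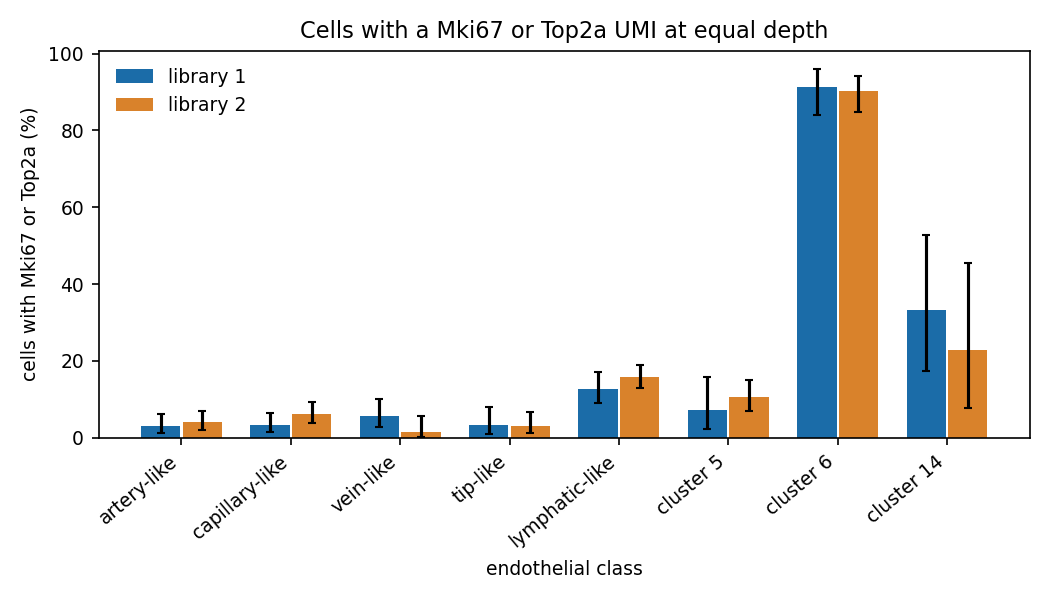
Share of cells with a Mki67 or Top2a UMI after thinning to 3000 UMIs (%, vertical axis) by endothelial class (horizontal axis) for libraries 1 and 2 (bars), with exact 95% intervals as error bars. Cluster 6 stood at 91.3% and 90.3%, and tip-like cells at 3.18% and 3.13%.

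Surface protein was compared between classes as mean tag counts per cell. ICAM1, an adhesion receptor for leukocytes, was highest among the named classes in vein-like cells (364 ± 70.1 tag counts per cell; SD, n = 2) and lowest in lymphatic-like cells (39.2 ± 10.5), a ratio of 9.40 ± 0.734 within libraries. Capillary-like cells had 128 ± 9.12, tip-like cells 119 ± 23.7 and artery-like cells 75.4 ± 14.9 ICAM1 counts, and cluster 5 had 257 ± 21.8. Tag barcodes without mRNA data held 5.72 and 21.3 ICAM1 counts in libraries 1 and 2. The lymphatic-like values rest on 294 of 303 and 504 of 603 cells in libraries 1 and 2. Whether the lymphatic-like cells without tag data differ in tag level is not known, so ratios to this class carry that limit. CXCR4, the CXCL12 receptor, was highest in tip-like (50.6 ± 6.75) and artery-like cells (37.0 ± 3.92), intermediate in capillary-like cells (22.1 ± 1.84), and near the rat IgG2a isotype tag (1.53 ± 0.516 over all endothelial cells) in vein-like (2.33 ± 0.453) and lymphatic-like cells (1.30 ± 0.197). Tip-like over lymphatic-like cells gave a CXCR4 ratio of 39.0 ± 0.702, where the IgG2a tag in lymphatic-like cells (1.29) was as high as their CXCR4 tag and the IgG2b tag was lower (0.224). Which isotype matches which antibody is not given in the sources used here, so how much of a low tag level is background is not known. As a share of all tag counts, summed over the cells of a class, that ratio was 10.3. Artery-like cells then came before tip-like cells (2.75 and 2.50 times the value of all endothelial cells). Cxcr4 mRNA was 42.8, 32.9 and 14.7 CPM in tip-like, artery-like and capillary-like cells, and vein-like and lymphatic-like cells, with 0.803 and 0.485 CPM, had too few UMIs to be ranked. Among the named classes VEGFR2 ran from 4.83 ± 0.830 in tip-like to 1.92 ± 0.219 in artery-like cells (ratio 2.51 ± 0.146), with IgG2a at 1.31 and IgG2b at 0.267 in the latter, and clusters 6 and 14 had 5.08 ± 0.0124 and 6.03 ± 0.851. As a share of all tag counts VEGFR2 was highest in lymphatic-like cells (3.17 times the value of all endothelial cells, against 1.23 in tip-like cells) and lowest in vein-like cells (0.324). The shares of VCAM1 and CD45 were also raised in lymphatic-like cells (2.47 and 2.05), where ICAM1, most of all tag counts, was lowest. Per cell, VEGFR2 in lymphatic-like cells was 0.908 times the value of all endothelial cells. VCAM1 (2.13 ± 0.0220 over all endothelial cells) and CD45 (2.38 ± 0.0512) were low in every named class and near the IgG2a tag in most, though above the IgG2b tag (0.289 ± 0.0875 over all endothelial cells). As a share of all summed tag counts of a class, of which ICAM1 made up most, the ICAM1 ratio fell to 1.19. The ratio of VCAM1 between artery-like and lymphatic-like cells then turned from 1.79 to 0.704. No test was run on the tags, so their SDs over 2 libraries are the only measure of spread. GENCODE vM21 lists Vcam1 (ENSMUSG00000027962) as a protein-coding gene on chromosome 3 from 116109949 to 116129688 of GRCm38 (mm10). Kdr (ENSMUSG00000062960) lies on chromosome 5 from 75932827 to 75978458 and Ptprc (ENSMUSG00000026395), the gene of CD45, on chromosome 1 from 138062861 to 138175708.

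**Figure D4:**
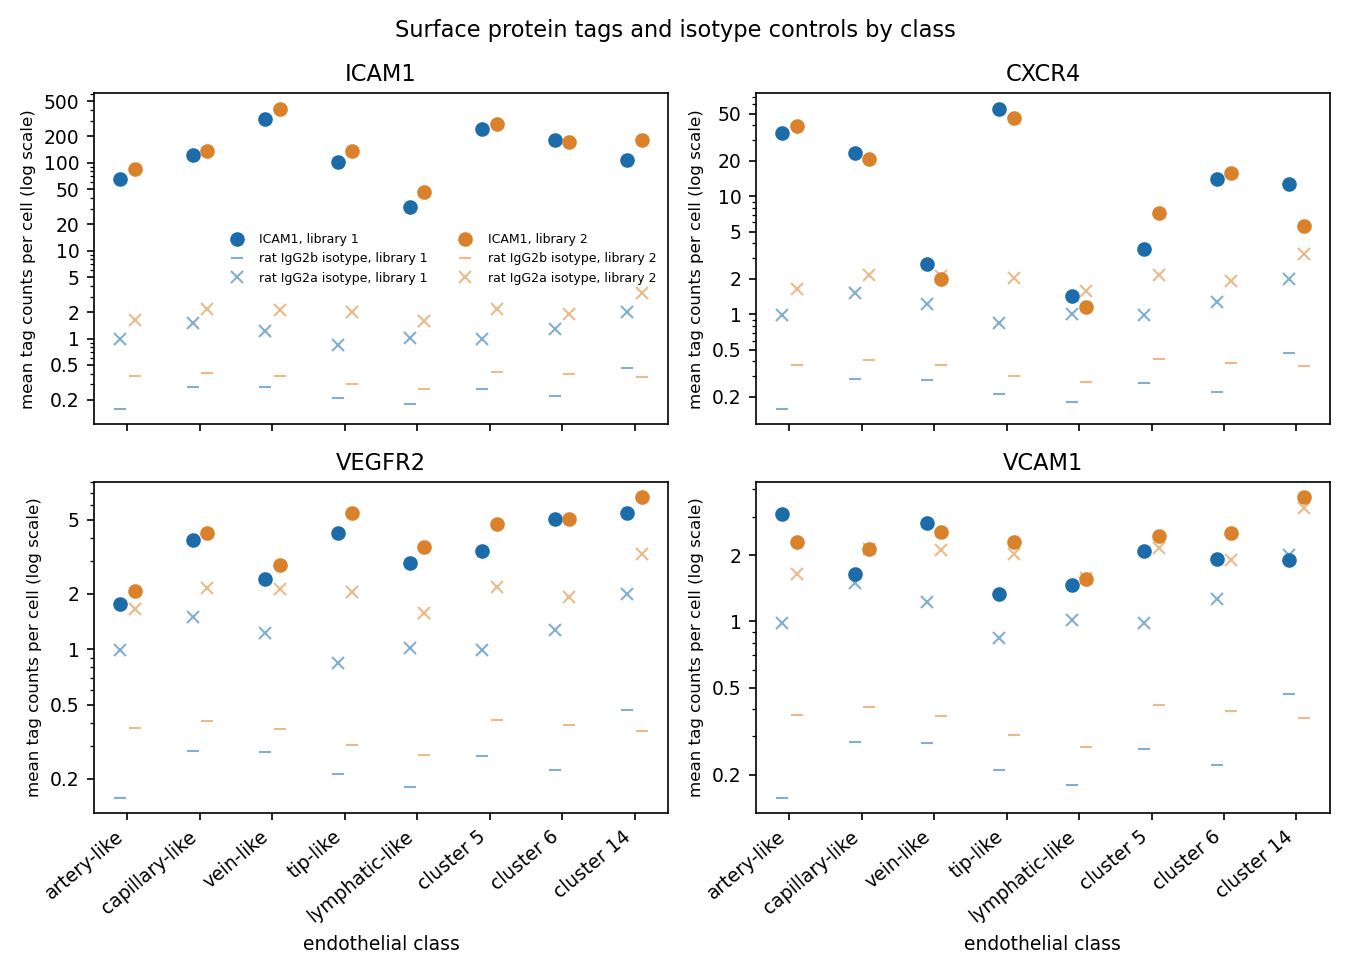
Mean tag counts per cell (log scale, vertical axes) of ICAM1, CXCR4, VEGFR2 and VCAM1 (panels; filled points) and of the rat IgG2a (crosses) and IgG2b (dashes) isotype tags by endothelial class (horizontal axis) for libraries 1 and 2 (colours). CXCR4 averaged 50.6 in tip-like and 1.30 in lymphatic-like cells.

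Whether protein and mRNA went together from cell to cell was examined within each library. Endothelial cells with an Icam1 UMI, after thinning to 3000 UMIs, carried 2.31 and 1.96 times the ICAM1 tag counts of cells without one in libraries 1 and 2, whereas both isotype tags together gave 1.07 and 0.993. For CXCR4 the ratios were 4.85 and 4.28 (isotypes 1.17 and 1.06), from 50 and 68 cells with a Cxcr4 UMI. For VEGFR2 they were 1.34 and 1.28 (isotypes 1.10 and 1.12). For VCAM1 library 1 gave 4.81 and library 2 gave 1.16 (isotypes 1.07 and 0.865), from 63 and 57 cells with a Vcam1 UMI, so library 1 alone carried the VCAM1 value. In capillary-like cells alone the ICAM1 ratios were 1.56 and 1.24 (isotypes 0.891 and 0.731), and the CXCR4 ratios were 3.97 and 1.76 (isotypes 1.63 and 0.89) from only 14 and 10 cells with a Cxcr4 UMI. For CD45, 0 and 1 endothelial cells had a Ptprc UMI, too few for a ratio.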

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

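Of the explanations weighed here, RNA of immune cells, doublets, and a difference between the libraries in tissue or recovery were chosen only after the result had been seen, and because the libraries form 1 group, no biological explanation was tested.

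Although the sort was for endothelial cells, 231 kept cells were pericyte-like and lay outside the comparisons. Most of them also carried Pecam1 and Cdh5 UMIs. Their mean tag counts were near those of capillary-like cells (ICAM1 145 against 128, CXCR4 22.8 against 22.1, VEGFR2 4.04 against 4.07). They were thus not shown to be pericytes alone. The CD45 antibody, which endothelial cells hardly bound, gave a mean of 1195 tag counts per cell in the few immune-like cells (1682 and 709 in libraries 1 and 2). UMIs of the tdTomato reporter, the gene behind the sort, were found in 38.9% of endothelial cells (38.3% and 39.3%). The tag libraries held 84468 counts that matched no antibody, a part of the data no comparison used.

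Cluster 5 had higher mRNA of Icam1, Cxcl10, Sele and immediate-early genes than the mean log level of the named blood endothelial classes, although Sele was higher still in vein-like cells. Part of this rise follows from how the cluster was formed. Transcription during cell preparation that had not yet reached the protein would leave the ICAM1 tag of cluster 5 near that of capillary-like cells, but the tag was 1.99 and 2.03 times as high in libraries 1 and 2, so the protein was higher as well. Against vein-like cells, however, the ICAM1 tag was only 0.769 and 0.659 times as high, with 1960 CPM of Icam1 mRNA in cluster 5 and 1817 CPM in vein-like cells, so transcription ahead of the protein could still have added to the mRNA. RNA of immune cells is unlikely, since the summed level of macrophage, mast cell and lymphocyte markers in cluster 5 was 0.132% of that in immune-like cells. A response to the preparation that had reached the protein, and one already present in the animal, could not be separated with these data.

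Cluster 16, a part of the vein-like cells led by Tmem108, Htr2b and Vwf, held 34 cells in library 1 and 1 in library 2. Its 20 leading genes were also higher in library 1 in the other vein-like cells (median log2 ratio of library 1 to library 2 of 1.55), as a shift of all vein-like cells of that library would predict. However, these genes were taken from a cluster almost only in library 1, so they may lean to that library by selection. The test therefore cannot decide whether all vein-like cells shifted. Doublets are unlikely, since the median UMIs of cluster 16 were 1.04 times those of the other vein-like cells of library 1 (7929 against 7593). A difference between the libraries in the tissue taken or the cells recovered stays open, because each library is 1 preparation and the 19.0% of vein-like cells of library 1 in cluster 16 cannot separate it from a difference between animals.

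CXCR4 tag counts were high where Cxcr4 mRNA was low in absolute terms, so antibody binding unrelated to the gene was weighed. Cells with a Cxcr4 UMI had more CXCR4 tag than cells without one, by 4.15 and 4.03 times the corresponding ratio of the isotype tags in libraries 1 and 2. Such binding, if the same in all classes, would not give this difference. The ratios pool all classes, however, so binding that differs between classes could also have raised them. In capillary-like cells alone the ratios were 3.97 and 1.76 (isotypes 1.63 and 0.89), the same direction but from only 14 and 10 cells with a Cxcr4 UMI. Binding at a level common to all cells was not excluded by these ratios.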

How the results depend on the processing

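Of the alternative values for named genes, 5330 were counted as kept, 377 no longer passed, 4 came to pass and 41 reversed. A value was counted as kept if its direction and, where there was a test, its side of the threshold stayed. Those that no longer passed were 109 without the replicate block, 62 with the Wald test, 55 with count splitting, 44 and 28 at resolutions 2.0 and 0.5, 42 with equal cell numbers, 27 with doublets kept, and 5 or fewer under each other alternative. For lists the corresponding numbers were 254, 76, 17 and 10. Leaving out either library leaves no test, so the 492 values of each such setting, all counted as kept, have no side of the threshold. Neither setting changed the direction of a named gene that had passed. For the largest rises and falls this was fixed in advance, because the rule required the same direction in both libraries. Without library 1 the sign turned for 4 values that had not passed, counted above as kept: Icam1 in tip-like cells (log2 0.42), and Kdr in artery-like (0.026), tip-like (0.009) and cluster 14 cells (-0.010). Changing TMM to DESeq2 size factors changed no call of a named gene, and kept 1540 of the 1553 calls for capillary-like cells, 5012 of 5075 for lymphatic-like cells and 3225 of 3333 for cluster 6. For every value given here that moved or reversed, the cause was not tested, except where fewer cells, genes or libraries make a count smaller by construction. Removing cluster 16, removing cluster 10, clustering without cell cycle genes and splitting the cells by sex were chosen after seeing the data. Cluster 5 did not form again at resolution 0.5, nor did cluster 14 with count splitting, at resolution 0.5 or with doublets kept, so those fits were not run.

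With 1 library at a time, the share of endothelial cells ranged from 14.3 to 18.3% for artery-like, 16.5 to 20.2% for capillary-like, 6.18 to 12.97% for vein-like, 9.28 to 9.54% for tip-like, 22.0 to 29.3% for lymphatic-like cells, 5.22 to 12.2% for cluster 5, 7.75 to 8.76% for cluster 6 and 1.07 to 2.17% for cluster 14. The dividing share ranged from 13.6 to 16.3% in blood endothelial, 3.00 to 3.96% in artery-like, 3.38 to 6.14% in capillary-like, 1.60 to 5.62% in vein-like, 3.13 to 3.18% in tip-like and 12.7 to 15.7% in lymphatic-like cells. Tag ratios of the highest to the lowest class ranged from 8.88 to 9.92 for ICAM1, 38.5 to 39.5 for CXCR4, 2.41 to 2.61 for VEGFR2, 1.47 to 2.11 for VCAM1 and 1.64 to 2.80 for CD45. Ratios with over without mRNA ranged from 1.96 to 2.31 for ICAM1, 4.28 to 4.85 for CXCR4, 1.28 to 1.34 for VEGFR2 and 1.16 to 4.81 for VCAM1.

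Shares of endothelial cells moved with the clustering. With the stricter cell filter, capillary-like cells held 25.1%, tip-like 9.07%, lymphatic-like 16.2%, cluster 5 15.6%, cluster 6 12.3% and cluster 14 0%. With no cell filter, capillary-like cells held 39.8%, tip-like 0%, cluster 5 4.58%, cluster 6 5.64% and cluster 14 0%. With doublets kept, cluster 6 held 9.29% and cluster 14 0%. At resolution 0.5, capillary-like cells held 23.8%, tip-like 16.1%, cluster 5 0%, cluster 6 9.34% and cluster 14 0%, and at resolution 2.0 cluster 6 held 7.25% and cluster 14 2.97%. With 2000 variable genes, tip-like cells held 11.1%, cluster 6 9.15% and cluster 14 0%. Without library centring, capillary-like cells held 24.5%, tip-like 6.04% and cluster 14 0%. Clustering without cell cycle genes gave capillary-like cells 29.3%, tip-like 5.48%, cluster 5 13.4%, and clusters 6 and 14 0%, and the dividing share then rose to 5.88% in artery-like, 19.7% in capillary-like and 20.6% in tip-like cells.

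The number of genes that passed changed by more than 1.5 times in these fits. The DESeq2 Wald test passed 1000 genes for artery-like against vein-like cells, 790 for capillary-like, 229 for tip-like and 3109 for lymphatic-like cells, 228 for cluster 5 and 1869 for cluster 6. Without the low-count filter 838 passed for tip-like cells and 862 for cluster 5. Tip-like cells gave 762 genes at resolution 0.5, 303 at resolution 2.0 and 831 split by sex. Cluster 5 gave 273 at resolution 2.0, 677 with count splitting and 1181 with doublets kept. Cluster 14 gave 1718 at resolution 2.0 and 508 with equal cell numbers. Smaller moves followed removal of cluster 16 (1910 genes for artery-like against vein-like cells, 1767 for capillary-like and 5280 for lymphatic-like cells; Ccnb1, Nusap1 and Cgnl1 no longer passed) and of cluster 10 (4390 for lymphatic-like cells; Birc5, Cdc20, Cenpf, Cks2 and Ube2c no longer passed).

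Without the replicate block, 1032 genes passed for capillary-like cells, 217 for tip-like cells and 70 for cluster 5, Icam1 in tip-like cells turned to log2 0.10, and in cluster 6 only 1 list passed. Lists that turned direction without the block, none of them passing in either fit, were the tagged proteins (adjusted p = 0.987), flow response (0.926) and transcription factors (0.926) for artery-like against vein-like cells, junctions (0.936) for capillary-like cells and leukocyte adhesion (0.803) for tip-like cells. No other gene count or list count of a comparison moved by over 1.5 times without the paired design.

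Single genes reversed as follows. For artery-like against vein-like cells, Kdr was log2 0.055 with doublets kept, 0.073 at resolution 0.5, 0.075 at resolution 2.0 and 0.11 with count splitting, and Aurkb was log2 0.49 without cluster 16. For capillary-like cells at resolution 0.5, Atf3 was log2 0.16, Cxcr4 -0.11, Icam1 0.48, Ifit1 0.024, Isg15 0.30 and Sema3d 0.63, and Isg15 was log2 0.20 with doublets kept. For tip-like cells at resolution 0.5, Afdn was log2 0.24, Aqp7 2.38, Atf3 -1.11, Cavin2 0.064, Ccl2 -0.30, Cxcl1 -0.48, Cxcl12 0.36, Dhrs3 0.42, Hspa1a -0.12, Hspa1b -0.066, Jup 0.56, Kdr 0.22, Sema6a 0.017 and Vcam1 -0.55. Also for tip-like cells, Kdr was log2 0.076 and Vcam1 -0.29 with doublets kept, Icam1 0.28 and Kdr 0.064 at resolution 2.0, Vcam1 -0.15 with count splitting and Icam1 0.028 with equal cell numbers. In cluster 5, Ptprb was log2 0.11 and Vcam1 1.01 with doublets kept, and Vcam1 was 0.38 with count splitting and 0.054 with equal cell numbers. In cluster 6, Cxcl10 was log2 -0.03 and Icam1 -0.21 at resolution 0.5, and Cxcr4 0.35 with count splitting. The value of Kdr, cluster 14 against the mean of named blood endothelial classes, was log2 -0.045 at resolution 2.0.

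With the correlation estimated per list, 0 lists passed camera for artery-like, capillary-like, tip-like and lymphatic-like cells and for clusters 5 and 14, and 1 for cluster 6. With fry, 7 lists passed for artery-like against vein-like cells, 1 for tip-like and 13 for lymphatic-like cells, 3 for cluster 5 and 4 for cluster 6. The direction turned under fry for flow response and transcription factors between artery-like and vein-like cells (adjusted p = 0.926 for both), leukocyte adhesion in tip-like cells (0.960), and the tagged proteins (0.903) and antigen presentation (0.797) in cluster 6, and none of these passed.

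Without thinning, the dividing share was 22.6% in blood endothelial, 6.09% in artery-like, 12.4% in capillary-like, 9.13% in vein-like, 9.37% in tip-like and 20.9% in lymphatic-like cells. Calling a cell by at least 2 UMIs of the whole cell cycle list gave 75.9%, 70.8%, 76.4%, 62.3%, 74.1% and 78.4% in the same order, a call that most cells met. As a ratio to both isotype tags, the ICAM1 ratio of the highest to the lowest class was 7.21 and that of CXCR4 37.4. As a share of all tag counts, the ratios were 1.19 for ICAM1, 10.3 for CXCR4, 1.67 for VEGFR2, 0.704 for VCAM1 and 0.637 for CD45, so the last 2 reversed. Without the 1% of cells with the most tags the ICAM1 ratio was 8.48. Ratios with over without mRNA were 2.79 for ICAM1, 5.27 for CXCR4 and 2.55 for VEGFR2 without thinning, 1.40, 2.87 and 1.23 in capillary-like cells alone, and 1.18, 4.01 and 1.24 as a share of all tag counts. The VCAM1 and CD45 tags of endothelial cells lay near the IgG2a tag and above the IgG2b tag, and the isotype that matches each antibody is not given in the sources used here.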

Other observations

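Several groups of cells had no place in the comparisons. Cluster 17, with 15 and 19 cells in libraries 1 and 2, was led by Ccl5, Rsad2, Cxcl10, Oasl1, Cxcl9 and Ifit2, genes of the interferon response. The lymphatic-like cells were made of 4 clusters. Cluster 1 (Lyve1, Ptx3, Ccl21a, Reln) held 124 and 423 cells, cluster 9 (Lcn2, Clca3a1, Foxp2) 100 and 61, the dividing cluster 10 35 and 82, and cluster 13 (Cldn11, Nts) 44 and 37. Cluster 1 thus rose from 8.99% of endothelial cells in library 1 to 20.6% in library 2. Cluster 15, with 15 and 24 cells, combined haemoglobin mRNA with the tip markers Apln and Esm1, and its Hbb-bs level was 1677 and 890 CPM against 46788 and 41356 CPM in erythroid-like cells.

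Pericyte-like cells made up 6.14% and 6.21% of the kept cells. Rgs5 UMIs were found in 98.9% and 98.6% of them, Pecam1 in 82.6% and 73.4% and Cdh5 in 81.5% and 71.9%, at median depths of 12783 and 11549 UMIs. A tdTomato UMI was found in 22.8% and 29.5% of pericyte-like cells and in 0 of 7 and 0 of 6 keratinocyte-like cells, whose median depths were 16495 and 14718 UMIs. Both libraries held cells of female and male mice: of the endothelial cells, 727 and 819 carried Xist UMIs alone and 474 and 934 Y-linked UMIs alone in libraries 1 and 2.

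The libraries differed within classes. Immediate-early and stress genes were higher in library 2 in artery-like, capillary-like, vein-like, tip-like cells and cluster 5 (18 to 21 of 22 genes), whereas 12 of 22 were higher in lymphatic-like cells. Interferon response genes were lower in library 2 in artery-like (median log2 ratio of library 2 to library 1 of -0.44), capillary-like (-0.57) and tip-like cells (-0.25) and in cluster 5 (-0.23). In vein-like and lymphatic-like cells their medians (-0.14 and -0.11) were near those of all genes (-0.15 and -0.08). Cell cycle genes were lower in library 2 in vein-like (-1.32) and artery-like cells (-0.26). They were higher in capillary-like (0.49), tip-like (0.16) and lymphatic-like cells (0.06) and in cluster 5 (0.75).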
